A study of Homo sapiens with 15 samples.

How the data were processed

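RNA was measured by mRNA sequencing in 15 libraries of HFL-1 cells, an established line of human fetal lung fibroblasts, in 5 lentivirus groups of 3 libraries each. Per the labels' protocols, cells were left with virus supernatant for 24 hours and then kept in complete medium for 2 days, RNA was extracted with Trizol, and libraries were made with the VAHTS mRNA-Seq V2 kit. Samples were placed in groups by the genotype and titles in the labels. The replicates are called independent there without saying what was independent, so the p-values measure only the spread between these samples, which may be technical.

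The deposited values are raw read counts per gene, 1 file per library. Per the submitters' processing notes, HISAT2, SAMtools, featureCounts and Subread 1.6.0 were used with genome build hg38, and the notes as used here give no role or order for them. The annotation release and the settings for strand and for reads that map to several places are not given in the sources used here. Reads of overlapping genes, of a gene and its antisense partner, and of near-identical copies therefore could not be told apart, which makes values of genes with close copies (ribosomal protein genes, FTL, AK4, EEF1A2, RNU6-1) uncertain. Each file lists 60649 gene identifiers, of which 60507 pair with a symbol in GENCODE 29 or the supplied name table, and 58381 match GENCODE 29, from which coordinates (hg38) were taken. No line of the files is a total or an unassigned class. The 37 mitochondrial genes had 0 counts in every library, so the list of 13 mitochondrially encoded RNAs had 0 members tested. Library totals ran from 15753494 to 26570167 counts.

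The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 5 groups (17062 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 15 libraries so that the groups shared 1 estimate of the spread. Each comparison used the quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Expression levels are CPM, counts scaled by TMM-scaled library sizes, given as mean ± SD of 3 libraries. The comparisons were PEX5 against Flag, each hairpin and the mean of both hairpins against shNC, the hairpins against each other, and shNC against Flag.

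The comparisons, tests, 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists cover peroxins, peroxisomal enzymes and transporters, taurine and cysteine metabolism, the p38 MAPK pathway, senescence regulators, p53 targets, secreted senescence factors, mitosis, DNA replication, interferon response, NF-kB targets, immediate early genes, collagens and matrix, contractile genes, the unfolded protein response, ATF4 targets, NRF2 and antioxidant genes, cholesterol synthesis, mitochondrial fatty acid oxidation, lysosome and autophagy, mitochondrially encoded RNAs, cytosolic ribosomal proteins, and markers of epithelial, of endothelial and mural, and of immune cells. Lists were tested with camera, which compares a list with the other genes, at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone. The named genes were PEX5, 19 genes fixed in advance around senescence, taurine, p38 and peroxisomes, the 6 largest rises and falls among called genes with a mean of at least 5 CPM whose groups did not overlap, and up to 3 members per list with the smallest adjusted p. Some of these genes are not reported here. Groups of 3 and 3 fail to overlap by chance for 10% of unchanged genes.

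Before use, the fit was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. Changes of 1.5-, 2- and 4-fold were recovered for 46.3%, 65.7% and 90.9% of genes in PEX5 against Flag, for 50.7%, 64.2% and 89.4% in shPEX5-1 against shNC, and for 49.3%, 71.6% and 86.4% in shPEX5-2 against shNC. There were 8, 6 and 3 false calls among 143, 142 and 141 calls. The recovery asked of 4-fold changes was lowered from 90% to 80% after the first simulated result had been seen. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom 2.2 to 24.2 over genes), so each library was counted as 1 replicate. No batch beyond the groups is given in the labels, and all files carry the same lane tag.

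The alternatives were RLE size factors, no filter on low counts, a stricter filter (1 CPM in 3 libraries and a mean of 5 CPM), a fit of only the libraries compared, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a block, and for lists fry and the estimated correlation. Chosen after the data were seen were the other control group in place of the planned one, the mean of both control groups, and the removal of genes with particular heptamers in the 3' UTR. For that, 16384 heptamers were tested in 11246 genes with a 3' UTR of at least 30 bases, in a linear model with GC content, length and expression level, against 1000 permutations (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Comparisons that share control libraries were set beside 20 simulations of unchanged groups. Plots were drawn with matplotlib 3.10.9.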

Results

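PEX5 is the receptor that carries newly made enzymes from the cytosol into peroxisomes. The series asked what its gain or loss does to gene expression in human fetal lung fibroblasts (HFL-1), with p38 MAPK signalling, taurine metabolism and cellular senescence as themes. Cells had received a Flag control vector, a PEX5 vector, a control hairpin (shNC) or either of 2 hairpins against PEX5 (shPEX5-1 and shPEX5-2). RNA was profiled on day 3 in 3 libraries per group. Library totals had a median of 20697567 counts, and 17062 genes were tested. Values are CPM as mean ± SD (n = 3) or log2 fold changes with their SE, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

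PEX5 itself (ENSG00000139197.11, chromosome 12, 7188685 to 7218574, forward strand, hg38) moved as the labels state. It stood at 29.7 ± 1.01 CPM in Flag and 955 ± 385 CPM in the PEX5 group, a rise of 5.01 on the log2 scale (SE 0.30, adjusted p = 2.43e-07). The PEX5 libraries differed among themselves, at 1183, 1171 and 510.4 CPM. Against 32.1 ± 2.97 CPM in shNC, PEX5 fell to 9.78 ± 0.551 CPM with shPEX5-1 (log2 fold change -1.72, SE 0.32, adjusted p = 0.000685) and to 6.78 ± 0.278 CPM with shPEX5-2 (-2.25, SE 0.33, adjusted p = 0.000138). The mean fall over both hairpins was -1.98 (SE 0.26, adjusted p = 6.25e-05). Neither the control groups (0.11, SE 0.28, adjusted p = 0.764) nor the hairpins (0.53, SE 0.37, adjusted p = 0.236) passed the test for a difference in PEX5.

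**Figure D1:**
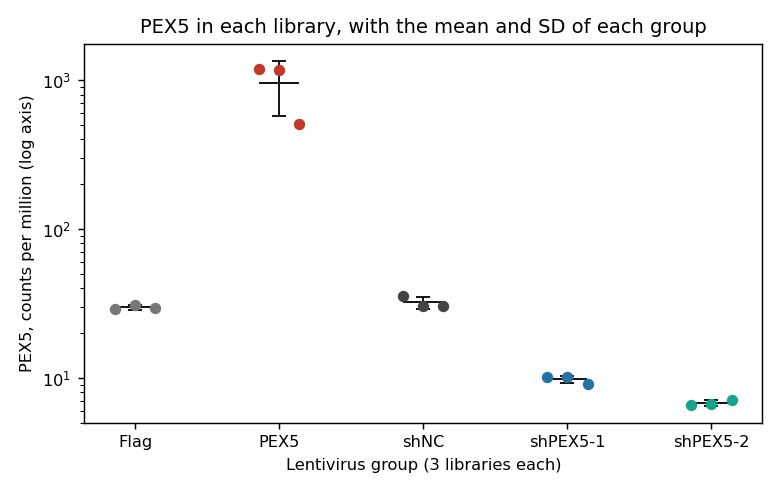
PEX5 in CPM on a log axis, 1 point per library and 3 libraries per group, with a dash for the group mean and bars for the SD. The PEX5 libraries lie between 510.4 and 1183 CPM, and the shPEX5-1 and shPEX5-2 libraries between 6.56 and 10.1 CPM, below every control library.

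With the PEX5 vector, genes of cell division rose and interferon-induced genes fell relative to Flag. All 24 tested mitosis genes rose, with a median log2 fold change of 2.65. Among them were BIRC5, a subunit of the chromosomal passenger complex (3.47, SE 0.16), and the proliferation marker MKI67, from 17.25 ± 1.58 to 87.15 ± 9.01 CPM (2.34, SE 0.15, adjusted p = 2.12e-08). Of 30 DNA replication genes 28 rose and 1 fell (median 1.45), led by the ribonucleotide reductase subunit RRM2 (3.08, SE 0.12) and thymidine kinase TK1 (2.89, SE 0.16). Of 37 interferon response genes 35 fell, 36 adjusted over the list alone, with a median of -2.26. MX1, an antiviral GTPase, went from 60.5 ± 2.22 to 2.30 ± 0.781 CPM (-4.71, SE 0.24, adjusted p = 3.43e-09). OAS2, IFI44L and IFI6, also induced by interferon, fell by 4.15, 3.84 and 2.99. Flag alone stood apart for this list: its libraries had medians of 1.79 to 1.81 relative to all libraries. All other libraries, the shNC and hairpin ones included, had medians of -0.74 to 0.052. Against shNC the list was not called in PEX5 (camera adjusted p = 0.346). The spindle protein DLGAP5 (3.60, SE 0.17), the kinesins KIF18B (3.37) and KIF2C (3.36) and the kinetochore protein SKA3 (3.35) were among the largest rises. The stress-induced factor ATF3 (-3.25, SE 0.14) was among the largest falls.

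Targets of p53 were lower with the PEX5 vector. Of 28, 24 fell and 1 rose (26 and 1 adjusted over the list alone; median -0.85). The cell cycle inhibitor CDKN1A (ENSG00000124762.14, chromosome 6, 36676460 to 36687339) fell from 3802 ± 371 to 1022 ± 41.5 CPM (-1.90, SE 0.072, adjusted p = 3.01e-14), and the growth factor GDF15 fell too (-2.42, SE 0.18). LMNB1, a nuclear lamina protein that is low in senescent cells, rose from 4.56 ± 0.112 to 31.3 ± 1.54 CPM (2.78, SE 0.15, adjusted p = 1.23e-12). Cholesterol synthesis genes rose in 19 of 25 cases and fell in 1 (median 0.68), for example LSS, lanosterol synthase (0.97, SE 0.051). NF-kB targets fell in 12 of 21 cases and rose in 1, 15 and 1 adjusted over the list alone (median -0.43), led by BIRC3 (-2.11, SE 0.15). Camera called these 6 lists at adjusted p = 6.18e-83 (mitosis), 2.02e-37, 2.69e-79, 4.35e-40, 5.04e-19 and 1.98e-05 in the order named. All 6 held with an estimated correlation (adjusted p = 0.000115, 0.000172, 0.000115, 0.00337, 0.00593 and 0.0227). So did immediate early genes, with 7 of 24 lower and 2 higher, 7 and 1 adjusted over the list alone (median -0.22, camera adjusted p = 0.000482, adjusted p = 0.0294 with an estimated correlation).

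Matrix and stress lists also differed between PEX5 and Flag. Of 38 collagen and matrix genes 23 rose, 25 adjusted over the list alone (median 0.43, camera adjusted p = 4.19e-08), with COL1A1, the main chain of type I collagen, at 0.76 (SE 0.054). That call was lost at adjusted p = 0.14 with an estimated correlation. PEX5 replicate 3 lay near Flag, with a list median of -0.31 relative to the mean of all libraries, against -0.0096 and -0.037 in replicates 1 and 2 and -0.37, -0.36 and -0.515 in Flag. Contractile genes rose in 11 of 20 cases (median 0.23, camera adjusted p = 0.00302; adjusted p = 0.184 with an estimated correlation), with ACTA2, smooth muscle actin, at 0.022 (SE 0.083). Of 24 unfolded protein response genes 14 rose and 2 fell, 15 and 2 adjusted over the list alone, such as the chaperone HSP90B1 at 0.72 (camera adjusted p = 7.61e-05; adjusted p = 0.123 with an estimated correlation). ATF4 targets fell in 16 of 28 cases and rose in 2 (median -0.39, camera adjusted p = 2.46e-06; adjusted p = 0.0551 with an estimated correlation).

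For the themes of the series, the lists were not called in PEX5 against Flag. Of 16 peroxins, the peroxisome assembly factors, 2 rose and 2 fell (median 0.018, mean -0.15, test direction lower, camera adjusted p = 0.729). Of 42 peroxisomal enzymes and transporters 17 rose and 5 fell, 18 and 5 adjusted over the list alone (camera adjusted p = 0.0707). Catalase (CAT) rose from 51.4 ± 1.71 to 72.6 ± 2.74 CPM. In taurine and cysteine metabolism 5 of 20 rose and 5 fell (camera adjusted p = 0.918; median -0.064 and mean -0.16 with the test pointing up). SLC6A6, the taurine transporter (ENSG00000131389.18), rose from 26.8 ± 0.699 to 53.7 ± 6.27 CPM (1.01, SE 0.088, adjusted p = 1.45e-08), and the taurine synthesis enzyme CSAD fell by 0.37 (adjusted p = 0.00124). CDO1 (0.23, adjusted p = 0.263) and ADO (-0.12, adjusted p = 0.168), which oxidise thiols, did not pass. Of 37 p38 pathway genes 8 rose and 9 fell (camera adjusted p = 0.151), with MAPK14, p38 alpha, at 0.23 (adjusted p = 0.0012) and MAPK11, p38 beta, at -0.074 (adjusted p = 0.555). Senescence regulators rose in 8 of 20 cases and fell in 5, 9 and 5 adjusted over the list alone (camera adjusted p = 0.136). CDKN2A stood at 0.46 (adjusted p = 0.000277), CDKN2B at -0.19 (adjusted p = 0.125) and the lysosomal galactosidase GLB1 at 0.33 (adjusted p = 7.55e-05). Of 36 secreted senescence factors 3 rose and 11 fell (median -0.25, camera adjusted p = 0.065). That list passed without Flag replicate 3 (adjusted p = 0.00312), PEX5 replicate 1 (0.0284) or PEX5 replicate 2 (0.02). PEX5 replicate 3 had a list median of -0.73 relative to the mean of all libraries. PEX5 replicates 1 and 2 had 0.44 and 0.51, and the Flag replicates had 0.36, 0.32 and -0.14. Replicate 3 was also the lowest of its group in shPEX5-1 (-0.61) and shPEX5-2 (0.24), as in Flag, but not in shNC. Without PEX5 replicate 3 the list was not called either. With the replicate number as a block the list was called (camera adjusted p = 0.00548). The cytokine IL6 was called at -1.85 (SE 0.57, adjusted p = 0.0267) but not without Flag replicate 1 (-1.62), Flag replicate 2 (-1.49), PEX5 replicate 1 (-2.08) or PEX5 replicate 3 (-1.46). Its call also ended with limma-voom (-1.65, adjusted p = 0.132), with only the libraries compared (-1.87, 0.169) and with no filter on low counts (-1.83, 0.0589). The chemokine CXCL8 stood at -2.13 (adjusted p = 0.0715) and passed without Flag replicate 3 (-2.62), as CDKN2B did (-0.28).

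The remaining lists were not called either in PEX5 against Flag. Camera gave adjusted p = 0.67 for NRF2 and antioxidant genes (10 of 29 higher, 8 lower, 11 and 8 adjusted over the list alone), and 0.101 for mitochondrial fatty acid oxidation (10 of 24 higher, 11 adjusted over the list alone). It gave 0.918 for lysosome and autophagy genes (8 of 33 higher and 6 lower, median -0.026, mean 0.0057, test direction lower) and 0.171 for ribosomal proteins (2 of 35 higher, 7 lower; 1 and 5 adjusted over the list alone). Markers of epithelial cells (1 of 6 higher, 0 adjusted over the list alone; adjusted p = 0.795), endothelial and mural cells (3 of 11 higher, 1 lower; adjusted p = 0.67) and immune cells (1 of 8 lower, 0 adjusted over the list alone; adjusted p = 0.171) gave no call. The immune list passed without Flag replicate 2 (adjusted p = 0.0283). In all, 3541 genes rose and 2974 fell, of which 472 and 806 changed at least 2-fold. With shNC in place of Flag as the control, chosen after the data were seen, 1638 of these 6515 calls were calls in the same direction. Mitosis (24 of 24 higher, median 1.31, adjusted p = 3.09e-33) and DNA replication (26 of 30 higher) stayed called, each at adjusted p = 0.00801 with an estimated correlation. ATF4 targets stayed called at 0.000245 (adjusted p = 0.279 with an estimated correlation). The camera direction turned for interferon response (adjusted p = 0.346), NF-kB targets (0.046), collagens and matrix (1.88e-07) and contractile genes (0.207). The turned calls of NF-kB targets and of collagens and matrix had adjusted p = 0.328 and 0.324 with an estimated correlation. The calls of p53 targets (0.875), immediate early genes (0.111), the unfolded protein response (0.338) and cholesterol synthesis (0.939) ended. Lysosome and autophagy genes (16 of 33 lower, 2 higher, 0.000607) and ribosomal proteins (18 of 35 lower, 0.000749) became called, with adjusted p = 0.279 and 0.856 with an estimated correlation.

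**Figure D2:**
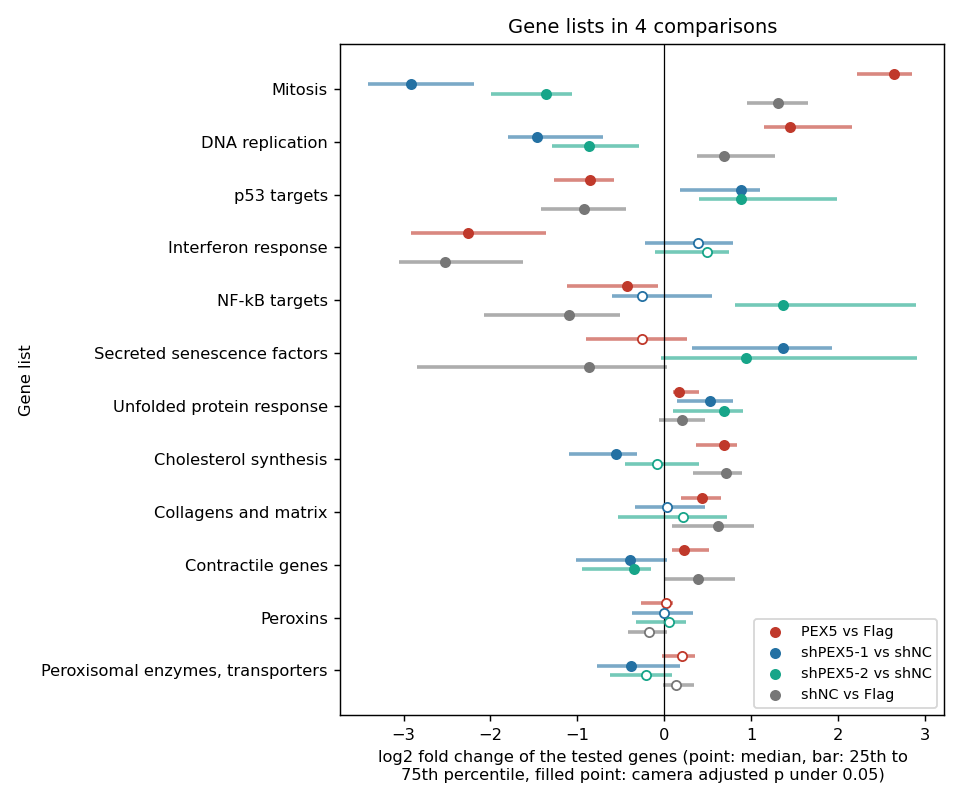
Log2 fold changes of 12 gene lists (vertical axis) in 4 comparisons (colours), with a point for the median of the tested members, a bar from the 25th to the 75th percentile, and filled points where camera's adjusted p was under 0.05. Mitosis genes have medians of 2.65 in PEX5 against Flag, -2.91 and -1.36 with the hairpins against shNC, and 1.31 in shNC against Flag.

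With shPEX5-1, cell division genes fell and p53 targets rose relative to shNC. Of 24 mitosis genes 23 fell (median -2.91), among them BIRC5 (-4.11, SE 0.21), the mitotic kinase CDK1 (-4.04, SE 0.35) and the checkpoint kinase BUB1 (-3.60, SE 0.19). MKI67 fell from 28.7 ± 5.86 to 1.94 ± 0.308 CPM (-3.86, SE 0.21, adjusted p = 5.69e-10). Of 30 DNA replication genes 26 fell and 2 rose, 27 and 2 adjusted over the list alone (median -1.46), with RRM2 lowest of all named genes at -4.15 (SE 0.15, adjusted p = 4.95e-16). Of 28 p53 targets 22 rose and 2 fell (median 0.89). CDKN1A rose from 1541 ± 91.8 to 4923 ± 426 CPM (1.68, SE 0.071, adjusted p = 8.64e-15) and BTG2, an antiproliferative factor, rose by 2.50 (SE 0.11). Secreted senescence factors rose in 17 of 36 cases and fell in 2 (median 1.37), for example INHBA, the activin A subunit (1.38, SE 0.067), and the adhesion molecule ICAM1 (1.90, SE 0.061). The libraries differed: the median of this list, as log2 CPM relative to the mean of all libraries, was 0.71, 0.47 and -0.61 in shPEX5-1 replicates 1, 2 and 3 and -0.68, -0.59 and -0.68 in shNC. Without shPEX5-1 replicate 3 the list stayed called (adjusted p = 2e-07). IL6 (-0.34, adjusted p = 0.706) did not pass. Camera gave adjusted p = 1.88e-20, 1.42e-07, 3.03e-09 and 1.27e-05 for these 4 lists, and none held: adjusted p = 0.0658, 0.126, 0.184 and 0.204 with an estimated correlation.

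Further lists called for shPEX5-1 concerned lipids, the endoplasmic reticulum and peroxisomes. Cholesterol synthesis genes fell in 19 of 25 cases and rose in 2, 20 and 2 adjusted over the list alone (median -0.55, camera adjusted p = 1.02e-06; adjusted p = 0.184 with an estimated correlation). SREBF2, the regulator of that pathway (-1.57, SE 0.050), and squalene epoxidase SQLE (-1.44, SE 0.064) fell. Unfolded protein response genes rose in 19 of 24 cases and fell in 4, such as the co-chaperone DNAJB11 at 1.27 (camera adjusted p = 0.000281; adjusted p = 0.204 with an estimated correlation). Lysosome and autophagy genes rose in 17 of 33 cases and fell in 9, 18 and 9 adjusted over the list alone, with the hydrolase CTSB at 1.58 (camera adjusted p = 0.00268; adjusted p = 0.204 with an estimated correlation). Of 42 peroxisomal enzymes and transporters 25 fell and 8 rose, 25 and 9 adjusted over the list alone (median -0.39, camera adjusted p = 0.019; adjusted p = 0.18 with an estimated correlation). CAT fell from 57.0 ± 1.46 to 19.9 ± 2.52 CPM. Contractile genes fell in 13 of 20 cases and rose in 2, with ACTA2 at -1.45 (camera adjusted p = 0.000893; adjusted p = 0.204 with an estimated correlation). Ribosomal protein genes fell in 24 of 35 cases and rose in 3 (camera adjusted p = 0.00151; adjusted p = 0.715 with an estimated correlation). NRF2 and antioxidant genes rose in 15 of 29 cases and fell in 4, 15 and 5 adjusted over the list alone, with ferritin light chain FTL at 1.70 and thioredoxin reductase TXNRD1 at 1.08 (camera adjusted p = 0.0128; adjusted p = 0.64 with an estimated correlation). Calls were also made for ATF4 targets (14 of 28 lower, 9 higher; camera adjusted p = 0.019; adjusted p = 0.413 with an estimated correlation), among them NUPR1, a stress-induced nuclear protein (-3.34). Immediate early genes were called as well (9 of 24 higher, 3 lower; camera adjusted p = 0.0239; adjusted p = 0.184 with an estimated correlation). That call of immediate early genes ended without genes holding a heptamer discussed at the end of the text (adjusted p = 0.234).

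The largest rises with shPEX5-1 were in MUC7, a salivary mucin, from 0.821 ± 0.81 to 55.2 ± 29.1 CPM (5.93, SE 0.81, adjusted p = 7.6e-05), COLEC12, a scavenger receptor (5.60, SE 0.15), and ZG16B, a secreted lectin-like protein of glands (5.47, SE 0.77). The GABA receptor subunit GABRR2 (5.39), the matricellular protein CCN5 (4.57) and the muscle filament protein DES (4.52) followed. The summed CPM of 38 gland markers was 73.1 to 200.3 CPM in these libraries and 3.04 to 7.18 CPM with shNC. Not called were peroxins (5 of 16 higher, 5 lower, adjusted p = 0.829), taurine and cysteine metabolism (11 of 20 higher, 6 lower, adjusted p = 0.715) and p38 genes (18 of 37 higher, 13 lower, 19 and 13 adjusted over the list alone, adjusted p = 0.405). Nor were interferon response (16 of 37 higher, 7 lower, adjusted p = 0.257) and collagens and matrix (14 of 38 higher, 12 lower, adjusted p = 0.885). Cell type markers gave no call for endothelial and mural cells (6 of 11 higher, 3 lower, adjusted p = 0.562), epithelial cells (1 of 6 lower, adjusted p = 0.829) or immune cells (3 of 8 higher including LYZ, which glands also express, and 1 lower, 0 lower adjusted over the list alone, adjusted p = 0.543). Senescence regulators (7 of 20 higher, 7 lower; median 0.12, mean -0.19, test direction lower, adjusted p = 0.898), NF-kB targets (4 of 21 higher, 9 lower; median -0.25, mean 0.24, test direction lower, adjusted p = 0.829) and mitochondrial fatty acid oxidation (6 of 24 higher, 12 lower, adjusted p = 0.672) were not called either. Within them SLC6A6 rose from 46.1 ± 2.41 to 106.5 ± 12.9 CPM (1.21, SE 0.085), and CSAD rose by 0.48. CDO1 fell by 1.15 (SE 0.17), ADO fell by 0.49, MAPK14 fell by 0.27, and MAPK11 stood at 0.031 (adjusted p = 0.777). LMNB1 (-2.16, SE 0.16), CDKN2A (-1.38, SE 0.094), CDKN2B (-0.61, SE 0.094) and COL1A1 (-0.35, SE 0.054) fell and GLB1 rose (0.37, SE 0.057). CXCL8 was called at 3.65 (SE 1.34, adjusted p = 0.0354) but not without shNC replicate 1 (4.04), 2 (3.66) or 3 (3.38), without shPEX5-1 replicate 1 (3.46) or 2 (3.43), with limma-voom (3.62) or with no filter on low counts (3.63, adjusted p = 0.0761).

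Over all genes, 5120 rose and 5299 fell with shPEX5-1, 1855 and 1784 of them at least 2-fold. Against Flag instead of shNC, 7164 of these 10419 calls were made in the same direction. With that control interferon response turned from higher to lower (35 of 37 lower, median -2.08; camera adjusted p = 4.37e-21; adjusted p = 0.0171 with an estimated correlation). NF-kB targets (16 of 21 lower, 1 higher, 0.000246) and collagens and matrix (26 of 38 higher, 4 lower, 1.77e-08) became called, with adjusted p = 0.0935 and 0.231 with an estimated correlation. Secreted senescence factors (15 of 36 higher, 13 lower) stayed called as higher at 0.0101 (adjusted p = 0.545 with an estimated correlation), but their median turned to -0.50 and their mean was -0.335. The camera direction of p53 targets turned (adjusted p = 0.536), and the calls of peroxisomal enzymes and transporters (0.294), immediate early genes (0.231), contractile genes (0.455), NRF2 and antioxidant genes (0.16) and cholesterol synthesis (0.793) ended.

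With shPEX5-2, NF-kB targets and immediate early genes rose relative to shNC and cell division genes fell. Of 21 NF-kB targets 20 rose (median 1.37), including ICAM1, from 45.0 ± 3.60 to 387.9 ± 23.0 CPM (3.11, SE 0.063, adjusted p = 2.89e-20), and BIRC3, an inhibitor of apoptosis (3.16, SE 0.17). Of 24 immediate early genes 18 rose and 2 fell (median 0.90), for example ATF3 (3.44, SE 0.14) and EGR2, a zinc finger factor (2.23, SE 0.13). Both lists held, with camera adjusted p = 3.41e-10 and 0.000111, and adjusted p = 0.0101 and 0.0481 with an estimated correlation. Of 28 p53 targets 24 rose and 3 fell (median 0.88), with CDKN1A at 2862 ± 117 CPM (0.89, SE 0.070, adjusted p = 3.16e-10) and BBC3, a mediator of apoptosis, at 2.13. Of 24 mitosis genes 23 fell (median -1.36), with MKI67 at 4.87 ± 1.31 CPM (-2.57, SE 0.18, adjusted p = 1.29e-08). Of 30 DNA replication genes 21 fell and 3 rose, 22 and 3 adjusted over the list alone (median -0.87), and PCNA, the polymerase clamp, rose by 1.26. Camera gave adjusted p = 6.75e-16, 4.51e-09 and 0.00206 for the p53, mitosis and DNA replication lists, and adjusted p = 0.0587, 0.0983 and 0.201 with an estimated correlation.

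Other lists called for shPEX5-2 were lost with an estimated correlation. They were secreted senescence factors (17 of 36 higher, 4 lower, median 0.94; camera adjusted p = 0.00281; adjusted p = 0.426 with an estimated correlation) and senescence regulators (11 of 20 higher, 6 lower; camera adjusted p = 0.00739; adjusted p = 0.0587 with an estimated correlation). The others were the unfolded protein response (17 of 24 higher, 3 lower; camera adjusted p = 4.59e-06; adjusted p = 0.0983 with an estimated correlation) and lysosome and autophagy genes (18 of 33 higher, 8 lower, 19 and 9 adjusted over the list alone; camera adjusted p = 0.00167; adjusted p = 0.201 with an estimated correlation). HYOU1, a chaperone of the endoplasmic reticulum, rose by 1.41, the sialidase NEU1 by 2.08 and the fucosidase FUCA1 by 2.29. Contractile genes (11 of 20 lower, 3 higher, 12 and 3 adjusted over the list alone; camera adjusted p = 0.00594; adjusted p = 0.284 with an estimated correlation) and ribosomal proteins (30 of 35 lower, 1 higher; camera adjusted p = 0.000666; adjusted p = 0.636 with an estimated correlation) were lower. ACTA2 fell by 0.77. The largest falls were in AK4, a mitochondrial adenylate kinase (-4.34, SE 0.21), CRABP2, which binds retinoic acid (-3.79, SE 0.11), ADCY7, an adenylyl cyclase (-3.55), and SEC61B, part of the protein translocation channel (-3.27, SE 0.091). EEF1A2, a translation elongation factor (-3.26), and XYLT1, which starts glycosaminoglycan chains (-3.13), followed. The largest rises were PIP, a secreted gland protein (6.38, SE 0.88), MUC7, at 75.3 ± 45.0 CPM (6.38, SE 0.80), and CXCL8, from 1.495 ± 0.742 to 112 ± 9.78 CPM (6.14, SE 1.21, adjusted p = 0.00112). The chemokine CXCL1 (5.94, SE 1.51), ZG16B (5.78, SE 0.76) and the granin SCG2 (5.18, SE 0.43) followed. The summed CPM of 38 gland markers was 101.6 to 279.9 CPM with shPEX5-2. With limma-voom the calls of PIP (6.61), CXCL1 (6.09) and CXCL8 (6.24) were lost.

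Lists not called for shPEX5-2 included peroxins (3 of 16 higher, 4 lower, camera adjusted p = 0.856) and peroxisomal enzymes and transporters (7 of 42 higher, 22 lower, 9 and 23 adjusted over the list alone, adjusted p = 0.114). They also included p38 genes (16 of 37 higher, 15 lower, adjusted p = 0.918) and taurine and cysteine metabolism (7 of 20 higher, 4 lower; median 0.011, mean -0.067, adjusted p = 0.699, test direction lower). SLC6A6 rose to 68.6 ± 3.44 CPM (0.57, SE 0.085, adjusted p = 5.84e-06), and CDO1 fell from 8.91 ± 0.265 to 2.81 ± 0.31 CPM (-1.66, SE 0.18, adjusted p = 2.18e-08). MAPK14 fell by 0.86 (SE 0.053) and MAPK11 by 0.50 (SE 0.091). ADO stood at -0.12 (adjusted p = 0.12). CAT was called at 0.19 (adjusted p = 0.0203) but not without shNC replicate 2 (0.18), shNC replicate 3 (0.17) or shPEX5-2 replicate 2 (0.17). CSAD was called at 0.24 (adjusted p = 0.0187) but not without shNC replicate 2 (0.20), shPEX5-2 replicate 1 (0.22) or 2 (0.20), or with no filter on low counts (0.23). LMNB1 fell (-0.54, SE 0.14), and CDKN2B (0.82), GLB1 (0.25) and COL1A1 (0.46) rose. CDKN2A (-0.054, adjusted p = 0.614) and IL6 (-0.076, adjusted p = 0.936) did not pass. Interferon response (18 of 37 higher, 5 lower) missed the threshold at adjusted p = 0.0547 and passed without shNC replicate 1 (0.0328), shPEX5-2 replicate 1 (0.0283) or shPEX5-2 replicate 2 (0.0214). It also passed without genes holding a heptamer discussed at the end of the text (0.0355). ATF4 targets (6 of 28 higher, 16 lower, adjusted p = 0.114) passed without shNC replicate 3 (0.0403). Collagens and matrix (19 of 38 higher, 11 lower, adjusted p = 0.953) and NRF2 and antioxidant genes (11 of 29 higher, 14 lower, adjusted p = 0.401) gave no call. The same held for cholesterol synthesis (8 of 25 higher, 10 lower; median -0.083, mean 0.022, test direction higher, adjusted p = 0.699) and mitochondrial fatty acid oxidation (7 of 24 higher, 8 lower; median -0.027, mean 0.083, test direction lower, adjusted p = 0.962). Nor were calls made for epithelial (1 of 6 higher; median -0.28, mean -0.29, test direction higher, adjusted p = 0.962), endothelial and mural (4 of 11 lower, 3 adjusted over the list alone, adjusted p = 0.234) or immune markers (2 of 8 higher including LYZ, 1 lower, adjusted p = 0.962).

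In all, 5037 genes rose and 5148 fell with shPEX5-2, 1494 and 1759 of them at least 2-fold. Against Flag, 6309 of these 10185 calls were made in the same direction. With that control the calls of mitosis (adjusted p = 0.586), DNA replication (0.778), p53 targets (0.505), secreted senescence factors (0.211; median 0.16, mean -0.38, test direction higher) and contractile genes (0.778) ended. NF-kB targets (9 of 21 higher, 3 lower, 0.00494) and immediate early genes (16 of 24 higher, 3 lower, 0.00195) stayed called, with adjusted p = 0.119 and 0.0584 with an estimated correlation. Interferon response turned from higher to lower (35 of 37 lower; camera adjusted p = 4.49e-24; adjusted p = 0.0131 with an estimated correlation). Cholesterol synthesis became called (21 of 25 higher, 2 lower; camera adjusted p = 1.02e-09; adjusted p = 0.0463 with an estimated correlation). So did collagens and matrix (24 of 38 higher, 8 lower, 1.64e-10), ATF4 targets (18 of 28 lower, 2 higher, 0.0111) and NRF2 and antioxidant genes (17 of 29 lower, 6 higher, 0.0396). These 3 had adjusted p = 0.116, 0.387 and 0.809 with an estimated correlation.

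**Figure D3:**
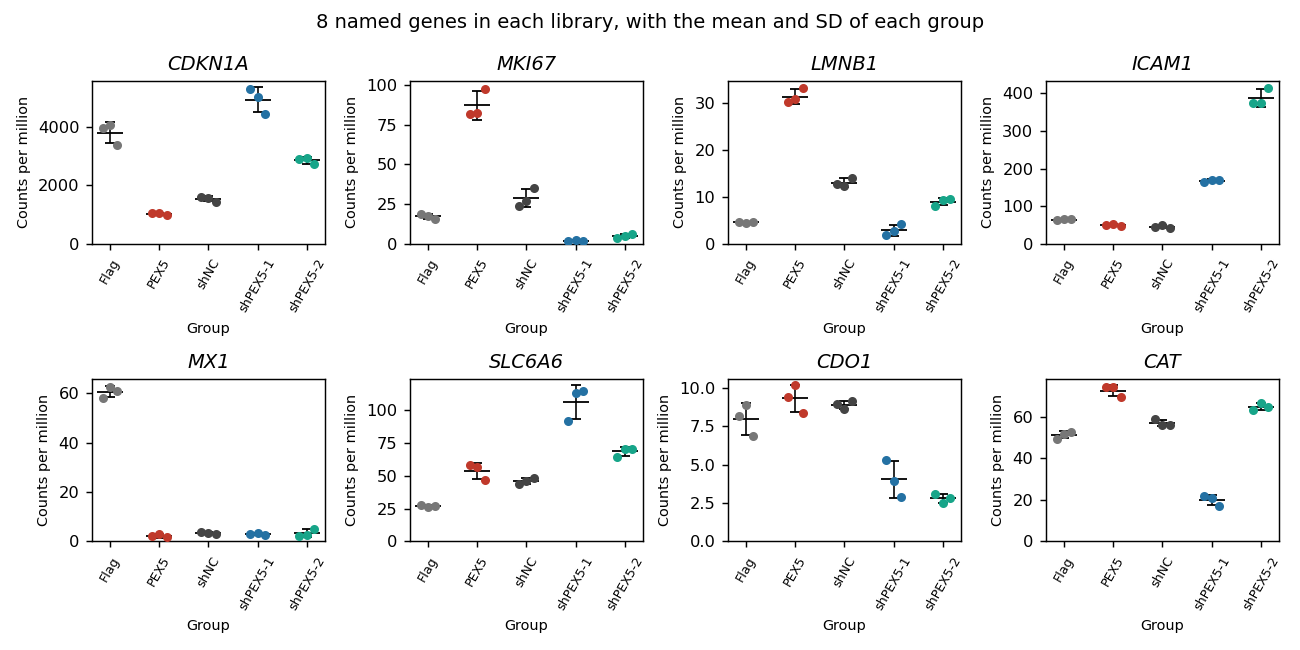
CPM of 8 named genes in every library (vertical axes start at 0), by group, with a dash for the mean of 3 libraries and bars for the SD. CDKN1A averages 3802 CPM in Flag, 1022 in PEX5, 1541 in shNC, 4923 in shPEX5-1 and 2862 in shPEX5-2, and MX1 averages 60.5 CPM in Flag and between 2.30 and 3.31 CPM in the other groups.

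Mitosis genes were lower (23 of 24) and p53 targets higher (22 and 24 of 28) with each hairpin than with shNC. The calls were lost for mitosis at adjusted p = 0.0658 and 0.0983 and for p53 targets at adjusted p = 0.184 and 0.0587 with an estimated correlation. Against Flag the mitosis call ended for shPEX5-2 (adjusted p = 0.586) and the p53 calls for both (0.536 and 0.505). Of the genes tested, 2468 rose and 2636 fell with both, against 1512 and 1599 for independent lists. Another 1997 were called in opposite directions, against 3109. Over the mean of both hairpins, RRM2 (-3.29, SE 0.11), BIRC5 (-3.29, SE 0.16), MKI67 (-3.21, SE 0.16), the somatostatin receptor SSTR1 (-3.17), TCF19 (-2.62) and the condensin subunit NCAPG (-2.58) were lowest. MUC7 (6.15, SE 0.77), PIP (5.92, SE 0.85), ZG16B (5.63, SE 0.73), GABRR2 (4.95, SE 0.32), CXCL8 (4.90, SE 1.19) and the U6 small nuclear RNA copy RNU6-1 (4.31, SE 0.21) were highest. The calls of PIP (6.26) and CXCL8 (4.93) were lost with limma-voom. CDKN1A (1.28, SE 0.064), BTG2 (2.52) and the cyclin-dependent kinase inhibitor CDKN1B (1.41) rose, as did SLC6A6 (0.89, SE 0.076), while CDO1 (-1.40, SE 0.14) and MAPK14 (-0.57, SE 0.045) fell. Of the lists, mitosis (23 of 24 lower, median -2.05) was called at camera adjusted p = 1.07e-22 and held with an estimated correlation at adjusted p = 0.0438.

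The other calls for the mean of both hairpins were lost with an estimated correlation. They were higher for p53 targets (24 of 28 higher, 2 lower, 25 and 2 adjusted over the list alone; camera adjusted p = 1.34e-16; adjusted p = 0.0594 with an estimated correlation). Camera also placed higher immediate early genes (14 of 24 higher, 2 lower), NF-kB targets (12 of 21, 2 lower) and the unfolded protein response (19 of 24, 4 lower), at adjusted p = 0.000254, 0.00123 and 1.31e-06. These gave adjusted p = 0.0594, 0.0793 and 0.0793 with an estimated correlation. For lysosome and autophagy (16 of 33 higher, 7 lower) and secreted senescence factors (18 of 36 higher, 4 lower) the camera adjusted p was 0.000188 and 1.27e-05, and adjusted p = 0.115 and 0.202 with an estimated correlation. They were lower for DNA replication (25 of 30 lower, 2 higher; camera adjusted p = 1.73e-07; adjusted p = 0.0594 with an estimated correlation). Peroxisomal enzymes and transporters (28 of 42 lower, 8 higher), contractile genes (13 of 20, 2 higher) and ATF4 targets (14 of 28, 8 higher) were lower at camera adjusted p = 0.0161, 0.00014 and 0.00748. These gave adjusted p = 0.0793, 0.118 and 0.292 with an estimated correlation. For cholesterol synthesis (14 of 25 lower, 4 higher, 15 and 4 adjusted over the list alone) and ribosomal proteins (29 of 35 lower, 2 higher) the camera adjusted p was 0.00748 and 9.27e-05, and adjusted p = 0.35 and 0.548 with an estimated correlation. Interferon response (13 of 37 higher, 5 lower) was not called at adjusted p = 0.0506 and passed without shNC replicate 1 (0.0339), shPEX5-1 replicate 3 (0.0259), shPEX5-2 replicate 1 (0.0349) or shPEX5-2 replicate 2 (0.0331), or without genes holding such a heptamer (0.0249). Peroxins (0.913), taurine and cysteine metabolism (0.913), p38 genes (0.511) and senescence regulators (0.196) were not called. Signs of median, mean and test differed for peroxins (0.024, -0.013, higher), taurine (0.15, 0.24, lower), p38 genes (-0.051, 0.066, higher), mitochondrial fatty acid oxidation (-0.11, 0.039, lower) and immune markers (-0.015, 0.29, higher). With Flag as the control, interferon response turned to lower in 36 of 37 cases (median -2.03; camera adjusted p = 3.31e-38; adjusted p = 0.00153 with an estimated correlation). The direction also turned for NF-kB targets (adjusted p = 0.489) and cholesterol synthesis (0.00216; adjusted p = 0.328 with an estimated correlation). Secreted senescence factors (13 of 36 higher, 10 lower) stayed called as higher at 0.014 (adjusted p = 0.552 with an estimated correlation), with a median of -0.11 and a mean of -0.36. Mitosis (20 of 24 lower) stayed called at 0.000262 (adjusted p = 0.328 with an estimated correlation). Collagens and matrix became called (24 of 38 higher, 3 lower; camera adjusted p = 3.28e-13; adjusted p = 0.11 with an estimated correlation). The calls of p53 targets (0.968), DNA replication (0.0907), peroxisomal enzymes and transporters (0.424) and contractile genes (0.489) ended.

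The hairpin comparisons share the shNC libraries. Both called 5104 genes in the same direction, against 3110 for independent lists. Among 20 simulations of unchanged groups against those libraries, at most 1 gene was called by both in the same direction. Those simulations called a mean of 0.45 genes for shPEX5-1, so their overlap was bound to be near 0 and cannot judge the observed one. Across genes, which are not independent replicates, the fold changes had r = 0.457, against a mean of 0.51 in the simulations. Their covariance was 0.49, against a mean of 0.0453 and a highest of 0.052 in the simulations, a difference of 0.445. As 3 control libraries cannot be split so that each part keeps 2, part of the excess may come from the shared controls. For example, genes with the heptamer GAAGAGC in the 3' UTR were lower in shNC than in Flag (t = -11.36). The same genes were higher with both hairpins against shNC (t = 6.23 and 8.0).

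The hairpins also differed from each other, NF-kB targets and cholesterol synthesis genes being lower with shPEX5-1. Of 21 NF-kB targets 17 were lower (median -1.39, camera adjusted p = 1.33e-08; adjusted p = 0.0231 with an estimated correlation), BIRC3 by -4.86 (SE 0.20). Of 25 cholesterol synthesis genes 19 were lower and 2 higher (median -0.64, camera adjusted p = 7.32e-07; adjusted p = 0.213 with an estimated correlation). Of 24 mitosis genes 21 were lower and 2 higher (median -1.31, camera adjusted p = 0.000706; adjusted p = 0.615 with an estimated correlation). NRF2 and antioxidant genes were higher in 17 of 29 cases and lower in 6, 18 and 6 adjusted over the list alone (camera adjusted p = 0.00318; adjusted p = 0.858 with an estimated correlation). Senescence regulators were lower in 11 of 20 cases and higher in 5 (adjusted p = 0.0376; adjusted p = 0.19 with an estimated correlation), a call that ended without shPEX5-1 replicate 2 (0.0635). DNA replication (16 of 30 lower, adjusted p = 0.0683) passed without shPEX5-1 replicate 1 (0.047), shPEX5-1 replicate 3 (0.0426) or shPEX5-2 replicate 2 (0.0364). Endothelial and mural markers (8 of 11 higher, adjusted p = 0.131) passed without shPEX5-1 replicate 3 (0.0256). CAT was lower with shPEX5-1 (-1.71), and MAPK14 (0.59, SE 0.054) and SLC6A6 (0.64, SE 0.083) were higher. Medians, means and tests differed in sign for secreted senescence factors (-0.27, 0.043, higher), collagens and matrix (-0.22, -0.065, higher) and contractile genes (-0.092, 0.11, lower), none of them called. Of all genes, 5349 were higher and 5595 lower with shPEX5-1 than with shPEX5-2.

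Gain and loss of PEX5 moved many genes oppositely when each was set against its own control. Of genes changed by both hairpins in 1 direction, 919 rose with the hairpins and fell with PEX5 and 1178 did the reverse, 2097 in all, against 430 and 547 for independent lists. Another 533 moved the same way in all 3 comparisons. CDKN1A (-1.90 with PEX5, 1.68 and 0.89 with the hairpins), BTG2 (-1.63, 2.50 and 2.55), MKI67 (2.34, -3.86 and -2.57) and LMNB1 (2.78, -2.16 and -0.54) moved oppositely. SLC6A6 rose in all 3 (1.01, 1.21 and 0.57). For CDKN1A the opposite movement depended on the control, as its mean with shPEX5-2 lay below that in Flag. Mean MKI67 lay above both controls with PEX5 and below both with each hairpin. Across genes, which are not independent replicates, the PEX5 and mean hairpin fold changes had r = -0.393 (Spearman's rho -0.364, covariance -0.27). The 2468 genes raised by both hairpins had a median of -0.16 in PEX5 against Flag (camera p = 5.1e-08, p = 0.000173 with an estimated correlation). The 2636 lowered ones had a median of 0.20 (camera p = 3.31e-15, p = 0.00214 with an estimated correlation). Against shNC, whose libraries the hairpin comparisons also use, the direction turned to that of the hairpins. The raised genes had a median of 0.16 (camera p = 2.77e-07, p = 0.000553 with an estimated correlation). The lowered ones had a median of -0.11 (camera p = 0.000662, p = 0.119 with an estimated correlation). For these sets the opposite movement was thus seen against Flag only. In 20 simulations with hairpin effects and an unchanged PEX5 group, sampling noise of the shared shNC libraries gave medians of 0.015 to 0.024 and -0.023 to -0.013. A real shift of the shNC libraries from the PEX5 group was not simulated. The mean hairpin fold changes also had r = -0.549 with those of shNC against Flag, which share the shNC libraries with opposite sign, against a mean of -0.586 in 20 simulations of unchanged groups. Their covariance was -0.425, against a simulated mean of -0.0343 and lowest of -0.0394, a difference of -0.391. With no filter on low counts the r of -0.393 was -0.147.

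**Figure D4:**
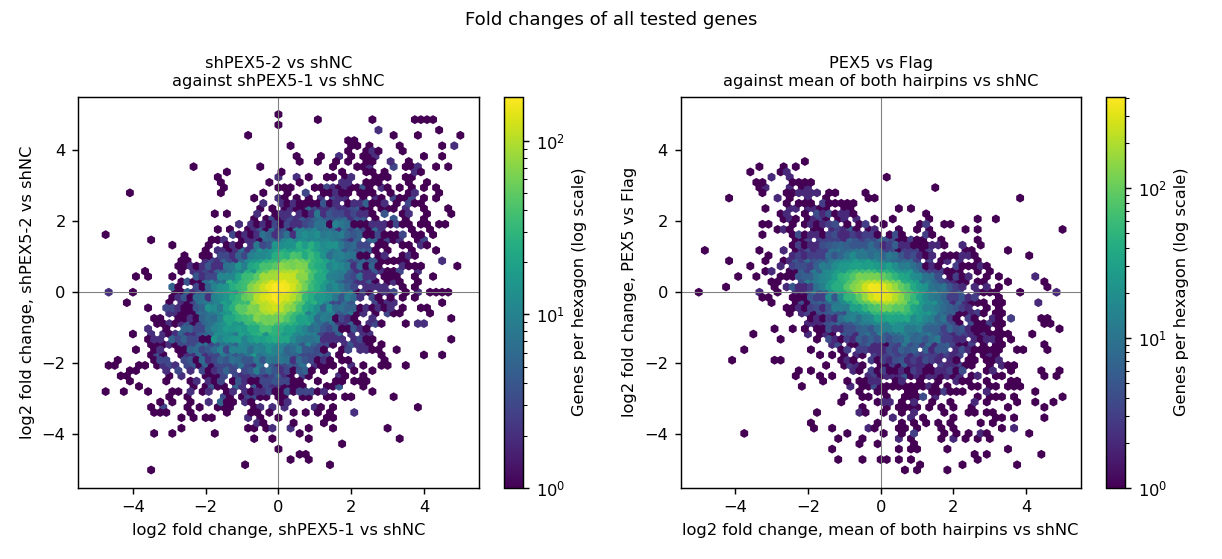
Log2 fold changes of the tested genes as hexagons coloured by the number of genes (log scale), shPEX5-2 against shPEX5-1 on the left and PEX5 against the mean of both hairpins on the right. The left cloud rises (r = 0.457) and the right one falls (r = -0.393), and 81 and 84 genes lie beyond the axis limits of 5.

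The control groups differed as well, interferon response genes being lower in shNC than in Flag. Of 37, 36 were lower, 37 adjusted over the list alone (median -2.52, camera adjusted p = 1.43e-58; adjusted p = 0.000403 with an estimated correlation). MX1 stood at -4.18 (SE 0.23) and IFI6 at -3.22. Lower too were p53 targets (23 of 28, median -0.92; camera adjusted p = 2.08e-25; adjusted p = 0.0207 with an estimated correlation), with CDKN1A at -1.30 (SE 0.071). NF-kB targets were lower in 18 of 21 cases (median -1.09; camera adjusted p = 3.23e-07; adjusted p = 0.0207 with an estimated correlation). Higher were mitosis (23 of 24, median 1.31; camera adjusted p = 1.03e-13; adjusted p = 0.0342 with an estimated correlation) and cholesterol synthesis (19 of 25, 1 lower, median 0.71; camera adjusted p = 1.47e-12; adjusted p = 0.0307 with an estimated correlation). Collagens and matrix were higher in 25 of 38 cases and lower in 1, 25 and 2 adjusted over the list alone (median 0.62; camera adjusted p = 3.9e-17; adjusted p = 0.0393 with an estimated correlation), with COL1A1 at 1.71 (SE 0.055). DNA replication (22 of 30 higher, 2 lower, 24 and 2 adjusted over the list alone; camera adjusted p = 2.92e-05; adjusted p = 0.0904 with an estimated correlation) was called only at the preset correlation. That also held for contractile genes (12 of 20 higher, 1 lower; camera adjusted p = 0.000296; adjusted p = 0.157 with an estimated correlation). Lysosome and autophagy genes (17 of 33 higher, 4 lower, 17 and 5 adjusted over the list alone) went from camera adjusted p = 0.0199 to adjusted p = 0.349 with an estimated correlation. Secreted senescence factors were called (19 of 36 lower, 6 higher; camera adjusted p = 0.0282; adjusted p = 0.509 with an estimated correlation), but not without Flag replicate 1 (0.0511) or shNC replicate 3 (0.0592). The unfolded protein response was called too (13 of 24 higher, 5 lower, 14 and 5 adjusted over the list alone; camera adjusted p = 0.0373; adjusted p = 0.401 with an estimated correlation). Its call ended without Flag replicate 1 (0.0511), Flag replicate 3 (0.0507) or shNC replicate 1 (0.0511). SLC6A6 was higher in shNC (0.78, SE 0.089), and GLB1, CDKN2A and CDKN2B were higher by 0.59, 0.76 and 0.78. Medians, means and tests differed in sign for taurine and cysteine metabolism (-0.14, -0.26, higher) and mitochondrial fatty acid oxidation (0.17, -0.041, higher), neither called. Over all genes 4362 were higher and 4305 lower in shNC. The comparisons of PEX5 and of shNC against Flag share the Flag libraries. They had r = 0.746 across genes, against 0.49 in 20 simulations of unchanged groups, and a covariance of 0.506 against a simulated mean of 0.0395 and highest of 0.0438, a difference of 0.467. Of their calls 4598 were in the same direction, against 1656 for independent lists. The simulations gave 0, but they called a mean of 0.1 genes for PEX5 against Flag, so that 0 cannot judge the observed overlap.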

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

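The tests of heptamers in held-out genes, of GC content, length and level, of loss of PEX5, of the Flag libraries against the other groups and of the shared Flag libraries were chosen after the result was seen.

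The hairpins, which target the same gene, differed from each other when compared directly. They differed in 10944 genes, among them 124 of the 143 genes named for the hairpin comparisons, and in 5 gene lists (camera adjusted p = 1.33e-08 for NF-kB targets, 7.32e-07 for cholesterol synthesis, 0.000706 for mitosis, 0.00318 for NRF2 and antioxidant genes and 0.0376 for senescence regulators). With an estimated correlation NF-kB targets held (adjusted p = 0.0231), and the others had adjusted p = 0.213, 0.615, 0.858 and 0.19. Of the named genes, 22 were called in opposite directions by the hairpins, as were 1997 of the 17062 genes tested. With shPEX5-1 minus shPEX5-2 on the log2 scale, the NF-kB members BIRC3 (-4.86), NFKB1 (-1.83), NFKB2 (-1.40) and BIRC2 (-0.83) were lower. So were the sterol genes TM7SF2 (-2.96), SREBF2 (-1.97) and DHCR7 (-1.50), JUND (-2.20), CAT (-1.71), SAMD9 (-1.65), CDKN2B (-1.43), COL1A2 (-1.41), CNN2 (-1.21) and COL1A1 (-0.81). Higher with shPEX5-1 were GCLM (2.01), FTL (1.90), TXNRD1 (1.89), NOTCH3 (1.70), MAP3K20 (1.46), PLIN2 (1.39), P4HA1 (1.18) and AGPS (0.92).

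Genes with a particular heptamer in the 3' UTR were lower in each hairpin group: CCCGCTG with shPEX5-1 (492 genes, t = -9.09), GAGGAAT with shPEX5-2 (1236 genes, t = -11.95) and GAAGAGC in shNC against Flag (1187 genes, t = -11.36). In that order, medians with and without the heptamer differed by -0.291, -0.223 and -0.176. Such genes were 6.05%, 15.02% and 16.06% of those called lower. With shNC as the control, genes with GAAGAGC were higher in shPEX5-1 (t = 6.23), shPEX5-2 (t = 8.0) and PEX5 (t = 14.5). These 3 comparisons thus share a shift of the shNC libraries. GC content, length and expression level were in the model, where the weakest t of -9.09 lay beyond the permuted range, which argues against these as the whole cause. A candidate explanation is microRNA-like activity of each hairpin, and heptamers picked in 5623 of the genes (for shPEX5-1 CCCGCTC, not CCCGCTG) ranked 6 or better among the lowest in the other 5623. Genes with 2 or more copies had the lower median in 2 of the 3 groups, where all 3 had been predicted, which leaves it open. The exception was GAGGAAT with shPEX5-2, with medians of -0.191 for 2 or more copies and -0.213 for 1 (one-sided permutation p = 0.6835). Genes with 2 or more copies also had longer 3' UTRs, which that comparison did not take into account. Loss of PEX5 as the cause was argued against: with the PEX5 hairpins it was not linked to, no heptamer had a t below -1.48, inside the permuted range, although both hairpins lowered PEX5.

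Lists called in PEX5 against Flag were called the same way in shNC against Flag, except immediate early genes (adjusted p = 0.226) and ATF4 targets (0.365). With an estimated correlation interferon response, p53 targets, NF-kB targets, mitosis and cholesterol synthesis held in both, while DNA replication was lost in shNC (adjusted p = 0.0904), collagens and matrix in PEX5 (0.14), and contractile genes (0.184 in PEX5, 0.157 in shNC) and the unfolded protein response (0.123 and 0.401) in both. Depth was argued against by libraries thinned to 1 total, where the interferon median stayed at -2.22. The covariance of 0.506 lay above the highest simulated value of 0.0438, which argues against sampling noise of the shared Flag libraries alone. The simulated groups held no real shift of the Flag libraries, so the covariance cannot exclude such a shift. A difference of the Flag libraries from the other groups may account for the interferon list (camera adjusted p = 0.346 in PEX5 against shNC), whose median relative to all libraries was 1.79 to 1.81 in Flag and -0.74 to 0.052 in the 12 others, but for p53 targets (0.875) this stays open, since the shPEX5-2 libraries (0.44) lay within the Flag range of 0.30 to 0.46. It was argued against as the whole cause for mitosis, which stayed higher in PEX5 against shNC (3.09e-33), while an effect of PEX5 stays open, untested, for the interferon and p53 lists.

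Transcripts of secretory glands (MUC7, ZG16B, PIP and LYZ, the last also in the immune list) were higher in both hairpin groups. The summed CPM of 38 gland markers, these included, was 73.1 to 279.9 in the 6 hairpin libraries and 3.04 to 10.4 in the 9 others. Much of that sum came from the genes first seen: in shPEX5-2 replicate 2 MUC7 stood at 124 and ZG16B at 87 CPM of 279.9. RNA of gland tissue is a possible explanation: 8 of 34 markers whose values had not been seen were raised (SMR3B, BPIFB2, MUC5B, CRISP3, AZGP1, PIGR, FDCSP and TCN1). However, 7 markers, HTN1, HTN3, SMR3A, BPIFA2, CST2, CST5 and AMY1A, had no count in any library, and SMR3B had none in 4 of the 6 hairpin libraries. A response of the fibroblasts cannot be told apart, as the sum differed 2.75-fold at most between replicates of a hairpin group, between the bounds set for either outcome.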

How the results depend on the processing

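The other control group, the mean of both control groups and the removal of genes with linked heptamers were chosen after the data were seen. Every count of changed genes stayed within 1.5 times its value under each alternative run. For the counts of each hairpin without genes holding a linked heptamer this was fixed in advance. There, 1560 genes for shPEX5-1 and 2190 for shPEX5-2 were dropped from the calls without a new fit, too few to pass that bound. A like count need not mean the same genes: with shNC as the control PEX5 gave 5558 calls, but 1638 of the 6515 planned calls recurred in the same direction. The count of genes that PEX5 moved oppositely and the correlation were not rerun with the other control. Leaving out 1 library gave 5250 to 6174 genes for PEX5 against Flag, 9799 to 10162 for shPEX5-1, 9399 to 9713 for shPEX5-2, 9202 to 10251 for the mean of both hairpins, 10285 to 10661 between the hairpins, 7527 to 8214 for shNC against Flag, 4612 to 4727 for both hairpins in 1 direction and 1762 to 2234 for those that PEX5 moved oppositely. The correlation ran from -0.398 to -0.364 without 1 library. It moved to -0.147 with no filter on low counts, and the cause was not tested, and to -0.434 with only the libraries compared. With the other control the direction of lists turned for interferon response (adjusted p = 0.346), NF-kB targets (0.046), collagens and matrix (1.88e-07) and contractile genes (0.207) in PEX5, for p53 targets in shPEX5-1 (0.536), for interferon response in shPEX5-1 (4.37e-21), shPEX5-2 (4.49e-24) and the mean of both hairpins (3.31e-38), and for NF-kB targets (0.489) and cholesterol synthesis (0.00216) in the mean of both hairpins. With an estimated correlation the turned calls of interferon response in the hairpin comparisons held. Those of NF-kB targets and of collagens and matrix in PEX5, and of cholesterol synthesis in the mean of both hairpins, were lost. Other than for interferon response, the cause of the turns was not tested. That control also gave 7 further list calls in the hairpin comparisons and 2 in PEX5, in the direction the list already had, of which cholesterol synthesis in shPEX5-2 alone held with an estimated correlation (adjusted p = 0.0463). An estimated correlation ended 47 of the 64 list calls made in 144 tests. Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, gave 49 further calls and ended none. Among named genes limma-voom ended 11 calls, while DESeq2 and RLE size factors ended none of the gene or list calls they were run for.

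With the replicate number as a block, 6917 genes were called for PEX5 against Flag, 10682 for shPEX5-1, 10412 for shPEX5-2, 10384 for their mean, 11153 between the hairpins, 8960 for shNC against Flag, 5310 for both hairpins and 2263 for the opposite set, with a correlation of -0.398. Same-numbered libraries correlated at -0.0458 to 0.179 in their deviations over genes, so the main fit did not pair them. A shared effect of the replicate number is not excluded by this. Replicate 3 had the lowest collagen and matrix median and the highest DNA replication median in every group. The collagen medians of replicates 1, 2 and 3 were -0.37, -0.36 and -0.515 in Flag and 0.21, 0.26 and -0.032 in shPEX5-1. Not every list did so, as the mitosis median in shPEX5-1 was highest in replicate 1. The block changed the calls of secreted senescence factors (0.00548) and CXCL8 (-2.11) in PEX5 against Flag, immediate early genes in shNC against Flag (0.0298) and senescence regulators between the hairpins (0.0734), and no other. At these depths and with 3 libraries per group, 46.3% of simulated 1.5-fold changes were recovered in PEX5 against Flag.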

Other observations

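The splits of the samples below were planned, and the heptamer scan and the count of splits with calls in all 3 comparisons were chosen after the result was seen.

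RNU6-1, a copy of the U6 small nuclear RNA whose reads near-identical copies share, stood at 0.131 CPM in Flag, 0.194 in PEX5, 0.802 in shNC, 18.6 with shPEX5-1 and 14.9 with shPEX5-2. Genes with the heptamer TGGTGCT in the 3' UTR were higher in both hairpin groups against Flag (t = 6.29 and 8.30). They had t = 4.08 in shNC against Flag, 4.51 with shPEX5-2 against shNC (permutation p = 0.138) and -5.07 in PEX5 against shNC, so the heptamer is not shown to be particular to the PEX5 hairpins. At 1 library size, 25404 to 26012 genes had a count in the Flag libraries, 24243 to 25062 with shPEX5-1, 22936 to 23797 with shPEX5-2 and 22737 to 23394 in the PEX5 and shNC libraries.

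Other splits of the same libraries were fitted the same way. For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real split called 6515, 10419, 10185, 10944 and 8667 genes for PEX5 against Flag, shPEX5-1, shPEX5-2, the hairpins against each other and shNC against Flag, and the highest other split 0 in each, so 1 of 10 splits gave as many. For lists, in the same order, the real split called 11, 13, 11, 5 and 11 and the highest other split 13, 12, 12, 8 and 14. As large were 6, 1, 3, 8 and 4 of 10 splits, the real one included. A further 100 splits were the real one and 99 drawn ones. For the mean of both hairpins only the real split called as many genes (10156, highest other 6367). As many lists (13, highest other 14) were called by 2, the real one included. Only the real split reached the overlap of both hairpins (5104, highest other 4218), the set that PEX5 moved oppositely (2097, highest other 0) and the correlation (-0.393, highest other -0.331). In these 100 splits each share was under 0.05, which speaks only to how these libraries were grouped. What was independent between replicates is not given, so a difference between cultures or infections is not excluded. For lists another split was larger, with 14 against 13. The opposite set was fixed at 0 in the other 99 splits, because none of them called genes in all 3 of its comparisons, so its share decides nothing.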
